A study of Cicer arietinum with 2 samples.

How the data were processed

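Leaf RNA of 2 chickpea (Cicer arietinum) cultivars, labelled PI and ICC, was measured on 1 custom Agilent array in 2 colours. Per the labels, 500 ng of total RNA of each cultivar was copied into dye-labelled cRNA, with PI as the control in Cy3 (green) and ICC as the test in Cy5 (red). Spike-in mix A went into the Cy3 reaction and mix B into the Cy5 reaction, per the labels. Each cultivar was represented by 1 sample and the dyes were not swapped on a second array in the samples used here. Dye and cultivar were therefore the same split, and a difference between them cannot be assigned to the cultivar alone.

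Spot intensity was deposited by the authors as the mean pixel brightness of each spot and the median brightness of its surroundings, for each channel, before any normalization. Images were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited software log ratio was on the log10 scale, as red over green after background subtraction and dye normalization, per the file headers. It was converted to log2 for use as an alternative, and it stood at 0 where both channels held surrogate values near background. The deposited p-value of each software ratio came from an error model of single spots on this array and was not used to make calls. A value table deposited by the authors held 1 log2 value per probe and cultivar, and its processing was found by setting it against the spot intensities. Its values followed the log2 mean signal of the same channel minus the 75th percentile, with an SD of the difference of 0.05 in PI and 0.08 in ICC. The medians of its columns were -1.85 for PI and -2.27 for ICC. Whether any background was removed before that step is not given in the sources used here, and none was apparent in the values.

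The array held 420288 spots, of which 3783 were controls and 416505 carried chickpea probes. The chickpea spots carried 334952 different probes, and 81553 of these had a repeat spot, read from probe names that ended in an added letter r. Their signals at the first and the repeat spot correlated at r = 0.988 in PI and 0.963 in ICC. Probe names fell into 4 classes: 3 of them carry a length (up to 1 kb, 1 to 2 kb and above 2 kb) and the last carries "xhyb", read here as cross-hybridising. What the lengths refer to, and how the cross-hybridising probes were chosen, is not given in the sources used here. The gene name of each of the 416505 chickpea spots was its probe name, and 0 names matched the 29938 genes of the reference table. Results are therefore given per probe, and the lists of leaf, stress and tissue marker genes chosen beforehand had no members that could be found. The rule for naming, fixed beforehand, was limited without gene names to 2 identifiers in each direction. These were the highest and the lowest log2 ratios among probes of at least 2-fold that were well above background in both channels, with spots of a single sign.

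Background was corrected with the normexp model in limma 3.58.1 under R 4.3.3, with an offset of 50, on the mean signal and the local background. The log2 ratio, ICC minus PI, was then normalized within the array by a loess curve with a span of 0.3 and 4 iterations. The curve was fitted to chickpea spots only. In total 454 chickpea spots marked by the software as uneven or as outliers were left out, and 0 chickpea spots were saturated. Spots of a probe were averaged, which left 334638 probes. A probe was called detected in a channel where any of its spots was well above background by the software's own call, and 159069 probes detected in at least 1 channel were kept. For probes detected in 1 channel only, the brighter value was set against the higher of the dim probe's own value and the lowest value among detected probes of that channel. This was done after scaling average intensities with the Aquantile method, and it is open to dye bias. The floor lay above the dim value for 0 of the probes detected in ICC only and for 1183 of those detected in PI only, so elsewhere the value is the measured ratio. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

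The steps were tested on simulated data built from this array for the comparison of ICC over PI, run over 334638 probes. Of 50 probes each with a true log2 ratio of -2, -1, 1 and 2, the median estimates were -1.61, -0.83, 0.84 and 1.77. The sign was right for 100% of each set. At the 2-fold threshold 74%, 14%, 16% and 98% of these sets were called, and 0% of 128480 unchanged probes. The unchanged probes carried only a smooth trend, background noise and the spot noise of repeated probes well above background in both channels. They held no dye effect of single probes, so the 0% is not a rate of false calls on the real array. The offset thus pulls ratios towards 0, and counts at 2-fold miss most probes whose true ratio lies at the threshold. Probes with a true ratio of 2 were called more often than those of -2. The simulated change was made in the ICC signal only, with the PI signal held. A change made in ICC lowers its signal towards the offset at -2 and raises it at 2, so this asymmetry cannot be read as a bias of the steps. At true ratios of 1 and -1 the shares were 16% and 14%.

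No p-value was computed, since each cultivar had 1 sample. The number of arrays, n = 1, limits the precision, and errors given as SD between spots describe a single hybridisation. The threshold of 2-fold, the normalization, the detection rule, the rule for naming and most alternatives were chosen before the data were examined. The alternatives were other background corrections, other normalizations, the software ratio, the value table, other filters and a 4-fold threshold. Another 4 alternatives were chosen after the data had been seen: a loess curve fitted to detected spots, for chickpea probes and for spike-ins, probes with both spots past the threshold, and the removal of cross-hybridising probes.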

Results

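The array measured leaf RNA of the chickpea cultivars PI and ICC side by side, as a gene expression trial of a probe set that was designed from transcriptome data. Each cultivar contributed 1 sample, so no difference below has a replicate check. The chickpea probes comprised 148503 of the up to 1 kb class (44.3%), 32474 of the 1 to 2 kb class (9.70%), 24789 of the above 2 kb class (7.40%) and 129186 cross-hybridising probes (38.6%). The median spot signal was 45.3 in PI over a median local background of 41. In ICC it was 108 over a background of 55. The brightest 1% of probes held 29.0% of the net signal in PI and 38.7% in ICC.

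The first question was how much of the probe set read RNA in leaves of each cultivar. PI leaf RNA was detected by 143734 of 334638 probes (43%) and ICC leaf RNA by 144015 (43%). The cultivars shared 128680 of these probes, which was 80.9% of the 159069 probes detected in either. Probes detected in PI only numbered 15054, and probes detected in ICC only numbered 15335. The cross-hybridising class was detected most often, by 62.2% of its probes in PI and 61.3% in ICC. The 1 to 2 kb class followed with 47.5% in PI and 47.9% in ICC. In the above 2 kb class the shares were 41.3% in PI and 42.0% in ICC. The up to 1 kb class was detected least often, by 25.5% of its probes in PI and 26.3% in ICC. Among probes detected in 1 cultivar, the up to 1 kb class had 7758 in ICC only against 6649 in PI only. The cross-hybridising class had 4698 in ICC only against 5826 in PI only.

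Of the 1200 negative control spots, 1.17% passed the same detection call in PI and 3.58% in ICC. With detection set at the 99th percentile of those controls, the share was 40.9% in PI and 35.1% in ICC, and it was higher in PI in each of the 4 classes. By that rule 25427 probes were detected in PI only and 6134 in ICC only. The up to 1 kb class then had 2992 in ICC only against 10078 in PI only, and the cross-hybridising class had 2018 against 11003. The order of the cultivars in detection therefore depended on the rule, overall and in the 3 classes named by length. The cross-hybridising class was detected more often in PI under both rules.

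**Figure D1:**
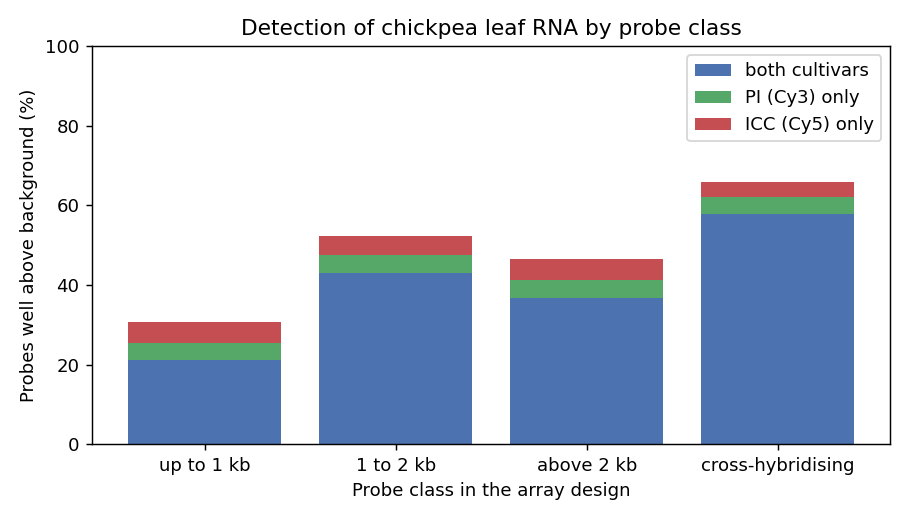
Share of probes well above background in each probe class of the array, in percent on the vertical axis, stacked as detected in both cultivars, in PI (Cy3) only and in ICC (Cy5) only. The cross-hybridising class reached 65.8% in either cultivar and the up to 1 kb class 30.7%.

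How many of the probes detected in 1 cultivar only differed by 2-fold depended on the setting. By the software ratio, 12349 of the 15335 detected in ICC only and 9964 of the 15054 detected in PI only were past 2-fold in favour of that cultivar. That ratio was taken without an offset against a channel not well above background, so its size is uncertain for these probes. After normexp and loess the numbers were lower. These probes are also part of the counts for the main comparison. Of the 15335 probes detected in ICC only, 1788 had a ratio of at least 2-fold in favour of ICC and 370 of at least 4-fold. The detection floor in PI lay above the own value of 0 of these probes, so here the floor gave no bound and the counts rest on fitted ratios against signal not well above background. Of the 15054 probes detected in PI only, 1709 were at least 2-fold higher in PI and 499 at least 4-fold. The floor in ICC replaced the own value of 1183 of these, and without it the counts were 1768 and 537. No fold could be given for 112 of the ICC probes and 199 of the PI probes, whose values came out under 1.

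The main comparison asked which probes differed between ICC and PI leaves. Higher signal in ICC by 2-fold or more was found for 13015 of the 159069 detected probes (8.18%). Higher signal in PI by 2-fold or more was found for 12410 (7.80%). The simulated data changed the ICC signal only, so they do not show whether the steps favour either cultivar, and the small excess in ICC stays unexplained. At 4-fold there were 2305 probes higher in ICC and 2592 higher in PI. Among the 128680 probes detected in both cultivars, 11227 were 2-fold higher in ICC and 10642 were 2-fold higher in PI. By the software ratio these were 15081 in ICC and 15934 in PI, so the balance between the cultivars depended on the setting. At 8-fold these probes numbered 550 in ICC and 495 in PI. Their log2 ratios had an SD of 0.84 across probes around a median of 0.01. The loess curve centres ratios near 0, so this median and the near balance of the counts are largely set by it. Without the curve, 61483 of the 159069 detected probes were 2-fold higher in ICC and 2703 in PI. The log2 signals of the cultivars, after background correction, the loess curve and Aquantile scaling, correlated at Pearson's r = 0.961 and Spearman's rho = 0.936. This was across the 128680 probes detected in both cultivars. The curve removes the trend between the dyes, which raises such agreement. Probes are not independent replicates, and both channels were read on the same spots. The authors' deposited software statistics listed 46252 spots as higher in ICC and 44842 as lower at a p-value threshold of 0.01, which came from the error model of single spots.

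The share of probes past 2-fold was lowest in the above 2 kb class among probes detected in both cultivars. It was 16.4% in the up to 1 kb class, 17.1% in the 1 to 2 kb class, 12.4% in the above 2 kb class and 17.8% in the cross-hybridising class. At a common distribution of brightness the shares were 18.4%, 17.3%, 16.4% and 15.8% in the same order. By the software ratio they were 26.8%, 25.5%, 21.8% and 23.6%, so which class was lowest depended on the setting. The median log2 ratio was -0.06 in the up to 1 kb class, -0.04 in the 1 to 2 kb class and -0.07 in the above 2 kb class. In the cross-hybridising class it was 0.07, and these signs held with the curve fitted to detected spots, the software ratio and an offset of 10. In that class 54.1% of the probes past 2-fold were higher in ICC, but the share was 47.2% with the curve fitted to detected spots and 49.7% with the software ratio. In the up to 1 kb class the share was 45.8%, and it was 46.1% and 45.4% under those settings.

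Of the probes named by the rule, GT_CPea_upto1kb_sp_0138707 was detected in both cultivars with a log2 ratio of 7.45 in favour of ICC and an SD of 0.04 between its 2 spots. Its mean signal was 62502 in ICC and 68.5 in PI. GT_CPea_xhyb_0018787 had a log2 ratio of 7.42 at its 1 spot. Its mean signal was 29767 in ICC and 116 in PI. The order of these probes depended on the setting, since an offset of 10 put them at 8.23 and 9.69. Without background correction they stood at 7.90 and 6.09, and by the software ratio at 8.97 and 6.62. The lowest ratio belonged to GT_CPea_upto1kb_sp_0125027, at -9.66 on 1 spot. Its mean signal was 250.1 in ICC and 56512 in PI. GT_CPea_upto1kb_sp_0023528 had a log2 ratio of -9.26 and an SD of 0.09 between its 2 spots. Its mean signal was 301.6 in ICC and 50262 in PI. The files do not pair these identifiers with genes.

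**Figure D2:**
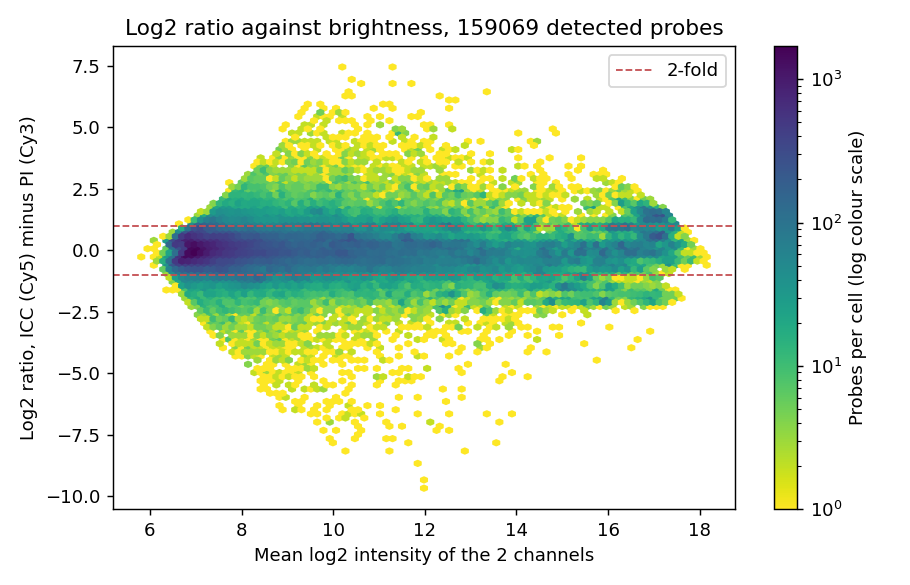
Log2 ratio of ICC (Cy5) minus PI (Cy3) on the vertical axis against the mean log2 intensity of both channels, for 159069 detected probes, with colour for the number of probes per cell on a log scale and dashed lines at 2-fold. The loess curve centred ratios near 0 over most of the range, and a cloud above the upper line appears among the brightest probes.

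The balance between the cultivars changed with brightness. Among the brightest 10% of the probes detected in both, 23.3% were 2-fold higher in ICC and 8.99% in PI, around a median log2 ratio of 0.27. Among the next 10%, 6.54% were higher in ICC and 17.4% in PI, around a median of -0.24. With a curve fitted to detected spots, chosen after this was seen, the brightest 10% held 9.68% higher in ICC and 12% higher in PI. The direction among the brightest probes therefore depended on the normalization. Of the brightest 5% of all probes by mean signal, 96.6% in PI and 96.5% in ICC were cross-hybridising, against 38.6% of the probes on the array. The shifts at high brightness were thus read mostly from that class, and they overlap with its lean in the main setting.

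Repeat spots of the same probe gave the error within the array. The cross-hybridising class had 0 repeat spots, so these errors cover only the classes named by length. Over 19467 probes with both spots well above background in both channels, the log2 ratios of the pairs correlated at r = 0.979. The SD per spot was 0.13, against an SD of 0.89 over probes. Of 3430 probes whose first spot was past 2-fold, 3095 (90.2%) were past it the same way at the repeat spot, and 0 were past it the opposite way. Over groups of 10% of these probes by brightness, the SD per spot ranged from 0.08 in the brightest to 0.18 in a middle group, and it was 0.14 in the dimmest. Over the 31473 repeated probes detected in any channel at any spot, the filter used for calls, r was 0.926 and the SD per spot 0.23. In that set 85.6% of first spots past 2-fold were so at the repeat spot. These errors say nothing of the spread between plants.

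**Figure D3:**
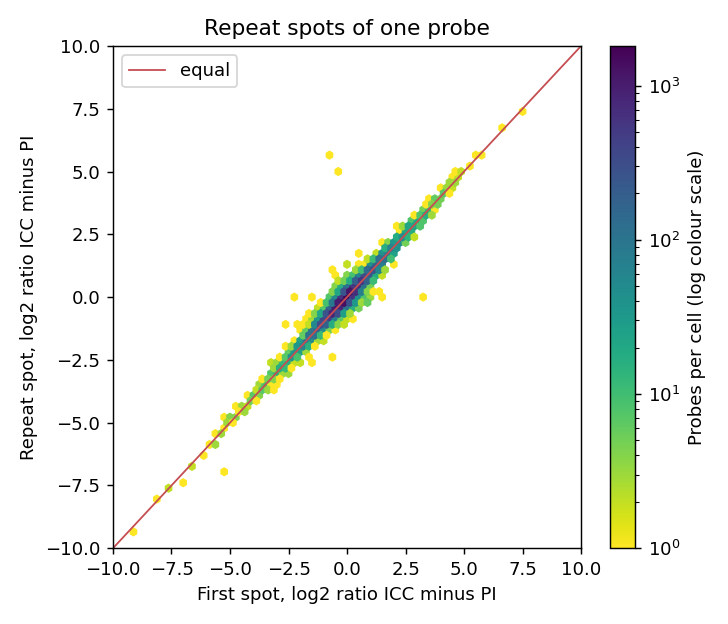
Log2 ratio of ICC minus PI at the repeat spot against that at the first spot, for 19467 probes well above background in both channels at both spots, with colour for the number of probes per cell on a log scale and a line of equal values. Most pairs lie along the line, at r = 0.979, and a few lie far from it.

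Spike-in RNA was added from different mixes to the Cy3 and Cy5 reactions, and its ratios were read after the curve fitted to chickpea spots. The 10 spike-in controls, on 63 spots each, had median log2 ratios between -3.32 for E1A_r60_n9 and 2.96 for E1A_r60_a22. E1A_r60_1 stood at 0.03, with an SD over its spots of 0.06, and at 0.14 with the curve fitted to detected spots. E1A_r60_a97, E1A_r60_3 and E1A_r60_a104 were higher in the Cy5 channel, at 1.75, 1.61 and 1.22. E1A_r60_a20, E1A_r60_n11, E1A_r60_a135 and E1A_r60_a107 were lower in it, at -0.54, -1.44, -1.61 and -1.65. With the curve fitted to detected spots E1A_r60_a20 stood at -0.81. The SD over the 63 spots ranged from 0.06 to 0.22. The mean absolute log2 ratio was 1.61, against 1.68 with the software ratio. The authors' deposited software statistics gave a slope of 0.971 and a correlation of 0.979 between observed and expected log ratios of these controls.

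**Figure D4:**
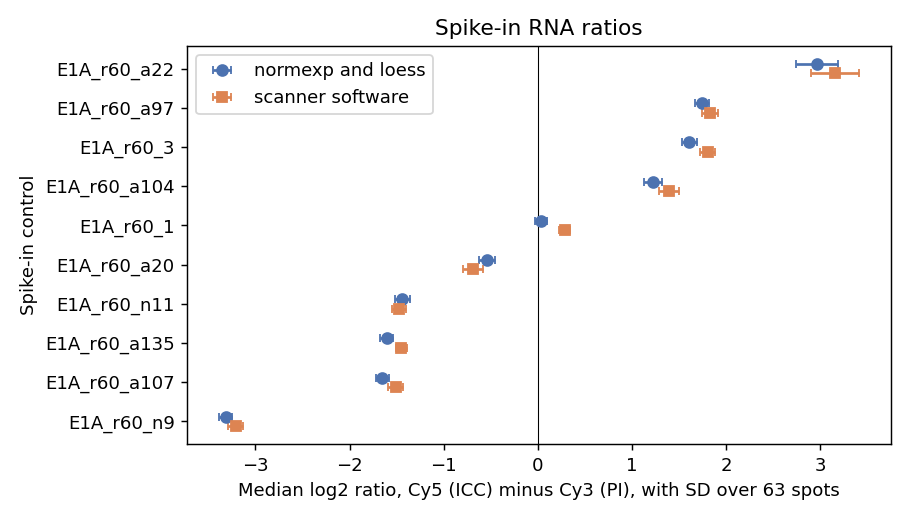
Median log2 ratio of Cy5 (ICC) minus Cy3 (PI) for each of the 10 spike-in controls, with bars for the SD over 63 spots, after normexp and loess (circles) and from the scanner software (squares). The settings differed by at most 0.25 for any control, with E1A_r60_n9 lowest and E1A_r60_a22 highest in both.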

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

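The control described here was noticed after the data had been seen, among spots that no comparison used. ERCC-00104_60, a probe for an external control RNA, was well above background in PI at 96.7% of its 60 spots. In ICC it was well above background at 88.3% of them. None of the other ERCC probes, out of 12 on the array, passed in over 3.33% of its spots in PI or over 10% in ICC. Its median signal over local background was 28 in PI and 121 in ICC, and its median log2 ratio was -0.10. No explanation was tested.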

How the results depend on the processing

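The curve fitted to detected spots, the count of probes with both spots past 2-fold and the removal of cross-hybridising probes were tests chosen after the results were seen. No paired analysis was possible because each cultivar had 1 sample. Probes past 2-fold, 13015 higher in ICC and 12410 in PI, stayed within 1.5 times under no background correction, offset 10, no filter on dim probes, detection in both channels, removal of saturated spots and the curve on detected spots. The filter removed no called probe and no spot was saturated, so those settings tested nothing. Median centring without a curve gave 61483 in ICC and 2703 in PI, or 95.8% in ICC against 51.2%, because it left the median of kept probes at 0.75; 2903 calls higher in PI turned sign. The software ratio gave 27430 and 25898, without an offset, and also called 84.3% of the ICC and 95.6% of the PI probes. The value table gave 24979 in ICC and 14749 in PI (62.9% in ICC); the cause was not tested. A 4-fold threshold gave 2305 and 2592. Fewer probes entered without the cross-hybridising class (5247 and 5840) and with both spots required (1860 and 2069, of 31473 probes). That class had 0 repeat spots, so requiring both spots also removed it, and these settings are not separate checks of the balance. Each of them, the 4-fold threshold and the curve on detected spots (11673 and 12601) put PI ahead. So did the software ratio among probes detected in both cultivars (15081 and 15934). Detection by negative controls was 40.9% in PI and 35.1% in ICC; the cause was not tested. Repeat spots correlated at 0.967 with an SD of 0.197 by the software ratio, and at 0.892 with 0.177 without the filter, which admits dim spots. The 4 named probes kept their direction in all 24 values recomputed for them, with a log2 size of at least 6.09, while 20 of these moved by more than the SD per spot. Of 20 values for the 10 spike-ins, by the software ratio and the curve on detected spots, 13 moved by more than their spot SD and 0 changed sign. Mean or brightest probe per gene, probe base composition, probe identity and gene list shifts were not run, because each gene name was 1 probe and no sequence was given. Counts among dim probes depended on the processing. Of the dimmest 10% detected in both cultivars, 0.0389% were past 2-fold, against 10.1% of the same probes by the software ratio, without an offset.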

Other observations

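The tests of the probe in the middle and of abundant transcripts were chosen after the results were seen, and so was the use of the spike-in series beside the refitted curve. Consecutively numbered probes of the longer classes alternated in leaf signal. In the 1 to 2 kb class the log2 signal in PI correlated at r = -0.252 between probes numbered 1 apart and at 0.321 between probes numbered 2 apart. In the above 2 kb class the values were -0.216 and 0.352. The log2 ratio of ICC minus PI, over pairs of probes detected in both cultivars, correlated at 0.499 and 0.597 between probes numbered 2 apart in these classes. In the up to 1 kb class the signal correlated at 0.02 between probes 2 apart, and in the cross-hybridising class at 0.04. These correlations are across probes, which are not independent replicates.

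Nearby spots sharing signal would not give this alternation, since the correlation at 2 apart was 0.320 in the 1 to 2 kb class among pairs over 100 grid lines apart. Between a pair of probes numbered 2 apart, each detected in both cultivars with a signal above 500 in PI, the probe in the middle was well above background in both channels in 16.2% of cases, against 42.2% of all probes of the 1 to 2 kb class. That value restates the alternation and tests no explanation of it. Probes of opposite strands, or of different ends of a transcript, taking turns in the numbering cannot be told apart without probe sequences. No biological explanation was tested.

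In the 1 to 2 kb and above 2 kb classes, probes of at least 4-fold were set against partners 2 numbers on and 2 numbers back. Where the partner was also past 2-fold the same way, they were higher in ICC in 342 of 594 cases (57.6%). Where the partner lay within 0.3 of 0 they were higher in ICC in 102 of 149 cases (68.5%). A sequence mismatch under a single probe may give a lone difference, and it would lean to the cultivar whose sequence the probes follow. Log2 ratios correlated at -0.018 between probes numbered 4 apart in the 1 to 2 kb class. In the above 2 kb class the value was 0.346, and -0.003 at 6 apart. A partner on 1 side may therefore be unrelated, and a partner near 0 need not mark a lone difference. The lean differed by 10.9 points with a 95% half-width of 8.73, from exact binomial intervals for counting error only. A probe could enter with either partner, and a pair with both members at 4-fold entered from each side. The cases are therefore not independent and the half-width is likely too narrow, so the 10 points set for this test were not settled. A mismatch, a dye effect of a single probe and a difference in the RNA cannot be told apart here, and a cultivar difference stays open and untested.

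The excess of probes higher in ICC among the brightest 10%, 14.3 points, may be a trend left by the loess curve. Refitting the curve on detected spots brought it to -2.32 points, inside the 5 points predicted beforehand, and this was first read as support for that explanation. The reading was then withdrawn, because a curve fitted to these probes removes part of any shift shared at one brightness, whatever its source, although it left -7.66 points in the next 10%. The software ratio gave -3.26 points after a lowess dye curve of its own, per the file headers; this was first read as evidence against more abundant transcripts in ICC, until that prediction was rewritten after the result. The control series DCP_20, DCP_22 and DCP_1 were taken for spike-in probes from names and ratios only, and were used after their values were seen. Over 5 probes of each, the range of log2 ratios was 0.27, 0.10 and 0.29 at first. It was 0.61, 0.16 and 0.23 after the refit, and 0.45, 0.04 and 0.06 by the software ratio. The dimmest probe of each series, well above background in PI at no more than 25% of its spots, was left out. Among these, DCP_22_9 stood at 1.70, and at 3.56 by the software ratio, so the ranges hold only for the brighter probes. On these values a leftover trend and a cultivar difference cannot be told apart.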
